A study of Mus musculus with 8 samples.

How the data were processed

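Polyadenylated RNA was sequenced from pancreatic islets of 12-week-old male mice, with 4 WT and 4 Wfs1KO samples. Per the labels, islets were isolated by collagenase digestion and density gradient purification, poly(A) RNA was selected from 200 ng of total RNA, and libraries were made with the NEBNext Ultra II RNA kit. Reads were demultiplexed with bcl2fastq, aligned with STAR 2.6.0a to mm10 and counted with HOMER 4.11.1, per the submitters' processing notes. Per the file headers, HOMER counted reads in exons of RefSeq genes, condensed to 1 entry per gene, with no normalization and no strand option given, so the deposited values are raw counts. The authors also deposited their own comparison, made with DESeq2 per the submitters' processing notes, whose settings are not stated. Its log2 fold changes, deposited by the authors, are of Wfs1KO over WT, a sign checked against the count table. Its p-values are unadjusted and adjusted values of that comparison, per the file headers. The transformed log2 values per library that the authors deposited beside it were not used here, nor were reads or counts per exon.

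The count table held 24537 genes, each symbol once, and no column of another sample. Of the symbols, 23828 were found in GENCODE M21 (GRCm38, the same build as mm10), and 98.6% of these overlapped the GENCODE gene on the same chromosome. Exon counts per library ranged from 15810830 to 27057617, and 15733 genes passed edgeR's filterByExpr by group (minimum count 10, minimum total count 15) and were tested. The common biological coefficient of variation was 10.7%. Because HOMER was given no strand option, exons that overlap a gene on the other strand may hold its reads. Of the named genes this applies to Neurod1, Ddit3, Txnip, Bcat1, Gm16702, T2, Trpm5, Slc7a2, Neurog3, Cd81, Zfp36l1, Tkfc, Mlxipl, Syt4, Itpr3, Cacna1a, Me1, Ccnd2, Cdkn1a, Bcl2, Icam1, Jun, Krt7, Eng and Egfl7. How reads shared by close paralogs were counted is not stated, which concerns Ins1 and Ins2, the trypsins, the amylases and the haemoglobins.

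Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, quasi-likelihood fit with robust=TRUE and F-test), limma 3.58.1 and DESeq2 1.42.0. A gene was called where its Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test was under 0.05, and "rose" and "fell" are used of called genes only. Adjusted p-values of genes are from this test and compare Wfs1KO with WT over all tested genes. Standard errors (SE) of log2 fold changes are the size of the fold change over the root of its F statistic. CPM values (counts scaled to a common library size) use TMM-scaled library sizes and are given as mean ± SD with n = 4 per genotype. The p-values measure the spread between separate islet samples of each genotype.

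The 30 gene lists, with 607 members of which 605 were in the table, the tests, the named genes and the alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera on the counts, with a preset correlation of 0.01 between genes, and with the correlation estimated per list, each adjusted over the lists by Benjamini-Hochberg. Camera compares a list with the other genes, while fry, an alternative, asks whether a list's own genes move on balance in 1 direction. Named genes were 20 key genes of islets and ER stress, the 10 largest rises and the 10 largest falls among called genes, and members of each list. The largest changes needed a mean of at least 5 CPM in the higher group and no overlap between genotypes. From each list, up to 4 called members with the smallest adjusted p were taken, and the most abundant member of each of the 8 lists for non-endocrine cells. Some genes that the rule takes are not reported here. Genes outside this rule are said to have been chosen after their values were seen. Called genes within 20 Mb of Wfs1 were compared with the rest by a two-sided Fisher's exact test.

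Alternatives were DESeq2, its size factors in edgeR, limma-voom with quality weights, no filter, a filter of 1 CPM in 4 libraries, the 20 most abundant genes left out, the acinar score as a covariate, other thresholds, fry, windows of 10 and 40 Mb, the replicate number as a block, and each library left out in turn. Keeping all entries per symbol could give no other value, as each symbol had 1. A block of replicates 1 and 2 against 3 and 4, the exon share as a covariate, each of these pairs of replicates alone, and Wfs1KO replicates 3 and 4 left out were added after the data were seen. The first principal component, the axis of largest variation between libraries (37.9% of variance), parted replicates 1 and 2 from 3 and 4 in both genotypes. The genotypes parted on the second component (28.4%). The shared replicate numbers come from the labels, which do not say what they mark. Deviations of same-numbered WT and Wfs1KO samples from their genotype means correlated across genes (genes are not independent replicates) at 0.153, 0.443, 0.269 and 0.188 for replicates 1 to 4. All were over 0.1, so pairing by number was allowed for in the replicate block and in splits and reassignments that regard pairs. The main fit had no block, so p-values given without mention of the block or of pairs ignore any pairing. WT replicate 2 correlated more with Wfs1KO replicate 1 (0.507) and WT replicate 3 with Wfs1KO replicate 4 (0.458). Every correlation between a replicate 1 or 2 and a replicate 3 or 4 was negative (-0.539 to -0.062). Those among replicates 1 and 2, and among 3 and 4, were all positive. The correlations therefore do not tell pairing by number from a division into replicates 1 and 2 against 3 and 4.

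The tests were tried on simulated data with 200 planted genes in each of 5 simulations of 4 against 4 libraries. Of planted 2-fold and 1.5-fold changes, edgeR found 77.6% and 63.9%, and 7.99% of its calls were false, more than the nominal 5%. DESeq2 found 82.4% and 66.1% with 16.9% false, and limma-voom 77.3% and 62.8% with 7.56% false. Camera called 0 of 150 unchanged lists, as did fry and camera with an estimated correlation, and camera with the preset correlation called 10 of 10 planted lists. The simulations changed 200 genes of at least 15447 tested, while 2970 of 15733 were called in the real libraries. The shares found and false depend on how many genes change, so they need not carry over. Each gene was simulated independently of the others. In the real libraries the estimated correlation within a list reached 0.884 (acinar markers). The simulations therefore do not show how often the list tests err where genes vary together.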

Results

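RNA was measured in 8 pancreatic islet samples of 12-week-old male mice, 4 WT and 4 Wfs1KO. Islets are the clusters of hormone-secreting cells of the pancreas, and Wfs1 encodes wolframin, a membrane protein of the endoplasmic reticulum (ER) that is mutated in Wolfram syndrome. Exon counts came to 19635870, 17146825, 15810830 and 21552731 in WT replicates 1 to 4 and to 27057617, 19900430, 16395855 and 20443320 in Wfs1KO replicates 1 to 4. Markers of acinar cells, the enzyme-secreting cells around the islets, took 5.44% ± 2.07 of exon counts in WT and 4.36% ± 2.97 in Wfs1KO (SD, n = 4 each). Their share ran from 1.34% in Wfs1KO replicate 3 to 8.46% in Wfs1KO replicate 4. The insulin genes Ins1 and Ins2 together took 14.84% ± 1.76 of exon counts in WT and 9.9% ± 1.13 in Wfs1KO, with no overlap between the genotypes.

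**Figure D1:**
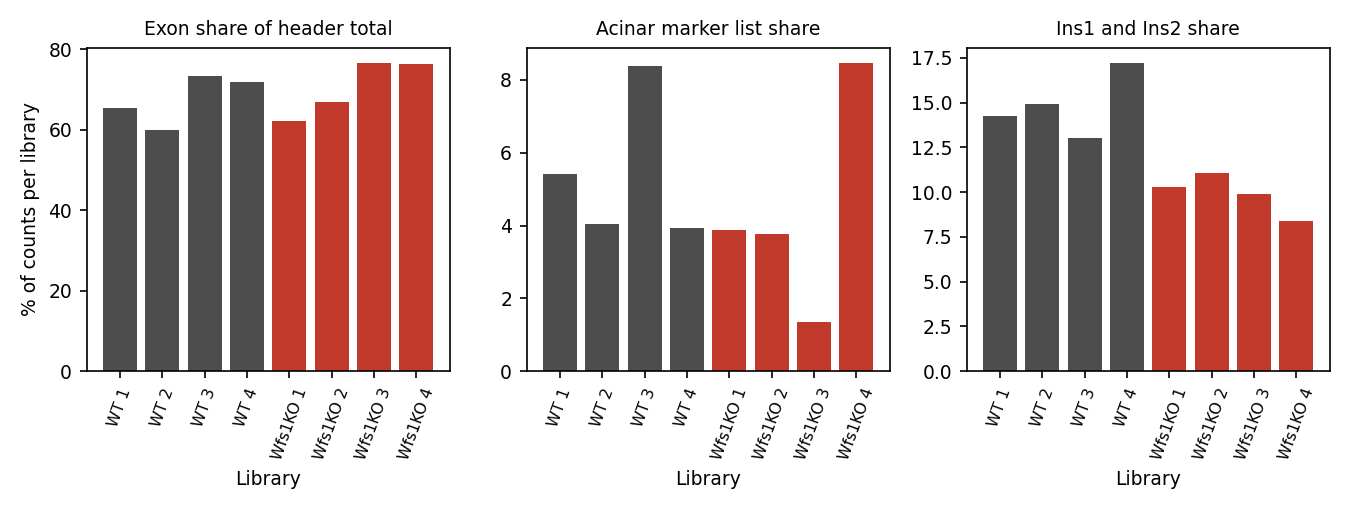
Share of exon counts in the header total, share of the acinar marker list and share of Ins1 plus Ins2 in exon counts (all in %), 1 bar per library, grey for WT and red for Wfs1KO. The Ins1 plus Ins2 share is 13.01% or more in each WT library and 11.06% or less in each Wfs1KO library, while the acinar share varies within both genotypes.

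The comparison asks how loss of Wfs1 changes gene expression in islets. Islets of Wfs1KO mice had less RNA of genes that define beta cells, the insulin-secreting cells, and more RNA of ER chaperones and of targets of the stress-induced transcription factors ATF4 and CHOP, although the list of these targets had an adjusted p = 0.157 with an estimated correlation. Mafa, a transcription factor of mature beta cells, was 5.20-fold lower (122 ± 14.9 CPM in WT, 23.6 ± 4.64 CPM in Wfs1KO), and Slc2a2, the glucose transporter GLUT2, was 2.87-fold lower (757 ± 59.3 to 264 ± 34.5 CPM). Aldh1a3, an aldehyde dehydrogenase used as a marker of dedifferentiated beta cells, was 15.9-fold higher (2.41 ± 0.412 to 38.2 ± 4.78 CPM). Hspa5, the ER chaperone BiP, was 1.505-fold higher (1354 ± 72.2 to 2038 ± 85.3 CPM). In each of these 4 genes every Wfs1KO library lay outside the range of the 4 WT libraries.

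Wfs1 itself (NM_011716, chromosome 5, 36966104 to 36988982 in mm10, minus strand) still had reads in every Wfs1KO library. It stood at 182, 156, 190 and 188 CPM in WT replicates 1 to 4 and at 101.1, 105, 125 and 98.9 CPM in Wfs1KO replicates 1 to 4, from 1998 to 3823 counts per library. The Wfs1KO mean was 0.599 of the WT mean, a log2 fold change of -0.74 (SE 0.08, 95% interval -0.90 to -0.58, adjusted p = 5.06e-05), lower in 4 of 4 Wfs1KO libraries. The counts cover all exons of the gene together, so they do not show which exons the remaining reads lie in.

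Of 15733 tested genes, 2970 (18.9%) were called, 1635 higher and 1335 lower in Wfs1KO, and 4893 had an unadjusted p under 0.05. Changes were mostly small, with a median log2 fold change of 0.41 among genes that rose and -0.34 among genes that fell, and 131 rose and 70 fell at least 2-fold. The genotypes did not overlap in 90.6% of called genes and in 6.82% of the others. Calling picks genes that part in these same libraries. The 2.86% expected by chance holds for genes not so picked and is no measure for the called ones. The largest changes were taken only from genes without overlap between genotypes. The largest rises were of Areg (log2 fold change 5.04, SE 0.27), which encodes the EGF receptor ligand amphiregulin, and of Aldh1a3 (3.99, SE 0.13). They were followed by Adm2 (3.98), the cystine transporter gene Slc7a11 (3.96), the cationic amino acid transporter gene Slc7a3 (3.66), the fucosyltransferase gene Fut1 (3.54), Serpina7 (2.83), Stc2 (2.35), the branched-chain amino acid transaminase gene Bcat1 (2.33) and Gdf15 (2.26), a secreted stress factor. The largest falls were of Caps2 (-3.15, SE 0.25), Mafa (-2.38, SE 0.14), Gm16702 (-2.03), the cation channel gene Trpm5 (-1.95), T2 (-1.83), Tmem215 (-1.83), the calcium sensor gene Vsnl1 (-1.82), the ciliary neurotrophic factor receptor gene Cntfr (-1.77), Bambi-ps1 (-1.73) and the potassium channel gene Kcnj12 (-1.70). Adjusted p-values of these 20 genes lay between 1.14e-09 (Aldh1a3) and 2.73e-04 (Trpm5). Gm16702 and T2 overlap on opposite strands, and Trpm5 overlaps Tssc4.

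**Figure D2:**
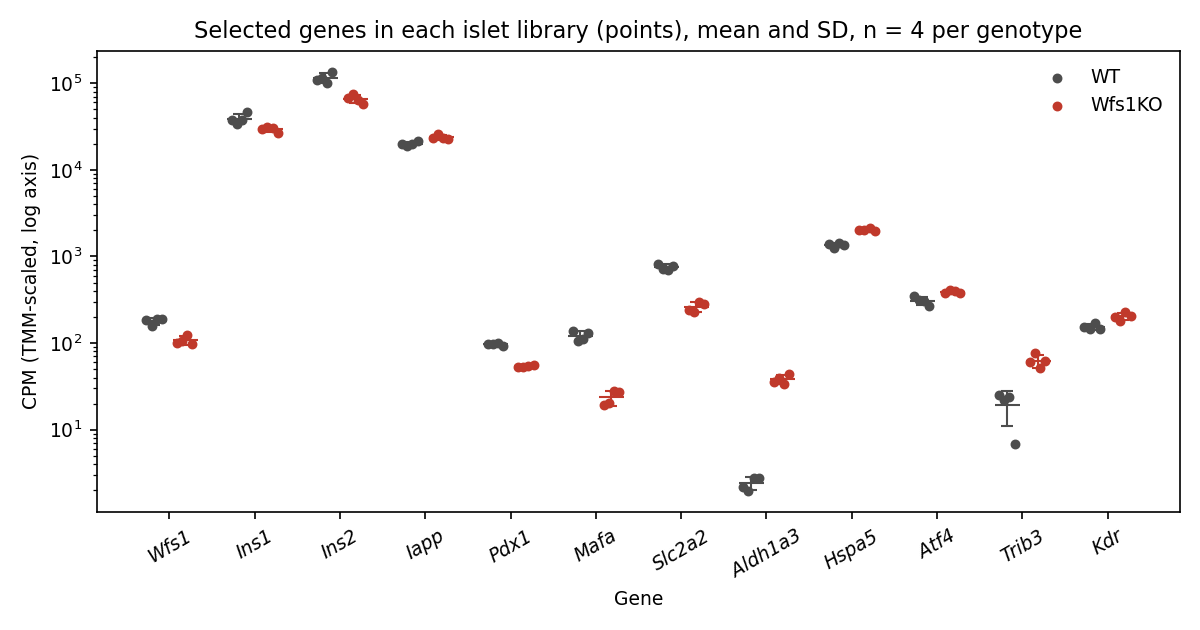
TMM-scaled CPM (log axis) of 12 genes in each islet library, grey for WT and red for Wfs1KO, with mean and SD (n = 4 per genotype). In all 12 genes the genotypes do not overlap, and in WT replicate 4 Trib3 stands below the other WT libraries.

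Genes of beta cell identity and glucose sensing fell as a group. Of 27 tested members 20 fell, 2 rose and 5 did not pass, and adjusted over the list alone 22 fell and 2 rose. The median log2 fold change was -0.46 (camera adjusted p = 7.01e-34, and adjusted p = 0.0164 with an estimated correlation). With the replicate block and an estimated correlation the list did not pass camera (adjusted p = 0.172). Besides Mafa and Slc2a2 (-1.52, SE 0.09, adjusted p = 2.60e-07), the granule docking gene Sytl4 fell by 1.26 on the log2 scale, the fatty acid receptor gene Ffar1 by 1.16 and the transcription factor gene Pdx1 by 0.84. Ins2 (-0.79, SE 0.10, adjusted p = 1.45e-04) and Ins1 (-0.41, SE 0.10, adjusted p = 0.00833) fell, and Ucn3 (-0.51), Neurod1 (-0.41) and Nkx6-1 (-0.31) fell as well. The 2 members that rose, named after their values were seen, were Tmem27 (0.37) and the amyloid peptide gene Iapp (0.24, adjusted p = 0.0398). The call of Iapp was lost without any 1 library other than WT replicate 4 (adjusted p 0.0593 to 0.119) and with the replicate block (0.0750). Endothelial markers were higher in the same comparison (median 0.49, 11 of 14 rose). Of 14 stellate cell markers 3 rose (median 0.57, camera adjusted p = 0.634 with an estimated correlation).

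Few markers of alpha cells changed, and some of delta and PP cells rose. Of 10 alpha cell markers 1 rose (the vitamin D binding protein gene Gc, 1.10), 1 fell (the amino acid transporter gene Slc7a2, -0.58) and 8 did not pass, with the same counts adjusted over the list alone (median 0.09, camera adjusted p = 0.659). The glucagon gene Gcg stood at 0.22 (SE 0.12, adjusted p = 0.243). Of 7 delta and PP cell markers 4 rose, 0 fell and 3 did not pass, and 6 rose adjusted over the list alone (median 0.33, camera adjusted p = 0.0233, and adjusted p = 0.378 with an estimated correlation). Those that rose were the somatostatin gene Sst (0.39), Hhex (0.33), Ffar4 (0.42) and Ghsr (0.41), while the pancreatic polypeptide gene Ppy stood at 0.21 (adjusted p = 0.422). Without WT replicate 2 the list no longer passed (adjusted p = 0.0502). Sst lost its call without WT replicate 1 or Wfs1KO replicate 2 or 3 (adjusted p 0.0506 to 0.0618), and Ffar4 without WT replicate 2 or 3 or Wfs1KO replicate 1, 2 or 3 (0.0606 to 0.0722). Ghsr lost it without any 1 of the 8 libraries (0.0518 to 0.115) and with the replicate block (0.0554). In the same libraries the medians of endothelial and stellate cell markers were 0.49 (11 of 14 rose) and 0.57 (3 of 14 rose).

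Some markers of dedifferentiation and of endocrine progenitors rose, and the list passed camera. Of 12 tested members 4 rose, 0 fell and 8 did not pass, and adjusted over the list alone 6 rose and 1 fell (median 0.47, camera adjusted p = 3.36e-08, and adjusted p = 0.0460 with an estimated correlation, but 0.266 with the replicate block as well). The 4 were Aldh1a3, Serpina7 (11.1 ± 4.14 to 78.7 ± 8.75 CPM), the progenitor transcription factor gene Neurog3 (4.87 ± 0.229 to 9.01 ± 0.894 CPM, log2 fold change 0.88) and Cd81 (0.36). Of 21 genes normally silenced in beta cells 3 rose, 0 fell and 18 did not pass, and 11 rose adjusted over the list alone (median 0.46, camera adjusted p = 9.35e-04, and adjusted p = 0.704 with an estimated correlation). These were the ornithine aminotransferase gene Oat (0.81), Lmo4 (0.60) and Zfp36l1 (0.67). Cd81 lost its call without WT replicate 1 or 2 or Wfs1KO replicate 1 or 3 (adjusted p 0.0622 to 0.0692), and Zfp36l1 without WT replicate 1 or 4 (0.0560 to 0.0569). In replicates 3 and 4 alone the silenced genes did not pass (median 0.14, adjusted p = 0.126), and without Wfs1KO replicate 1 their median was 0.29. Higher in the same comparison were 11 of 14 endothelial markers (list median 0.49) and 3 of 14 stellate cell markers (list median 0.57).

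Chaperones and genes of ER-associated degradation rose as a group. Of 32 members 27 rose, 0 fell and 5 did not pass, and 29 rose adjusted over the list alone (median 0.51, camera adjusted p = 8.32e-34, and adjusted p = 0.0460 with an estimated correlation). Derl3, a component of ER-associated degradation, rose by a log2 fold change of 1.76 (SE 0.08, adjusted p = 1.31e-08), Creld2 by 0.67, Selenos by 0.63 and Hspa5 by 0.59 (SE 0.07, adjusted p = 5.40e-05). Sdf2l1, a chaperone cofactor, rose from 59.4 ± 4.42 to 119 ± 6.31 CPM. Xbp1, a transcription factor of the unfolded protein response whose total RNA was counted here without regard to splicing, stood at 0.10 (adjusted p = 0.318). Of 36 targets of ATF4 and CHOP 27 rose, 1 fell and 8 did not pass, and adjusted over the list alone 30 rose and 1 fell (median 0.61, camera adjusted p = 2.90e-25, and adjusted p = 0.157 with an estimated correlation). They included Slc7a11 (1.61 ± 0.651 to 24.6 ± 5.19 CPM), Stc2, the serine synthesis gene Psat1 (1.80), the asparaginyl-tRNA synthetase gene Nars (0.64) and Atf4 itself (0.35, SE 0.07, adjusted p = 0.00395). Ddit4, named after its value was seen, fell by 0.32. Ddit3, which encodes CHOP, stood at 0.77 (SE 0.23, adjusted p = 0.0592), higher in 4 of 4 Wfs1KO libraries than in any WT library, and passed without WT replicate 4 (0.00339), with the replicate block (0.0379), with DESeq2 (0.00853) and with limma-voom (0.0444). Trib3, a CHOP target, rose (1.70, SE 0.38, adjusted p = 0.0239), but not without WT replicate 2 or 3 or Wfs1KO replicate 1, 2 or 4 (0.0536 to 0.0641) nor with the replicate block (0.0917). With the replicate block and an estimated correlation, no list passed, with adjusted p = 0.172 for the ER chaperones and for the beta cell genes and 0.266 for the dedifferentiation markers. Beside these groups, endothelial markers stood at a median of 0.49 (11 of 14 rose) and stellate cell markers at 0.57 (3 of 14 rose).

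Metabolic genes moved in both directions. Of 11 glucose-responsive targets of the transcription factor ChREBP 5 fell, 2 rose and 4 did not pass, and adjusted over the list alone 6 fell and 2 rose (median -0.19, camera adjusted p = 0.0112, and adjusted p = 0.378 with an estimated correlation), and without WT replicate 4 the median was -0.30. The fructokinase gene Khk (-0.55), the ATP citrate lyase gene Acly (-0.49), Mlxipl, which encodes ChREBP (-0.58), Acaca (-0.33) and Pklr (-0.31) fell, while Tkfc (0.35) and Arrdc4 (0.32) rose. Acaca, Pklr and Arrdc4 were named after their values were seen, and Arrdc4 lost its call without WT replicate 2 or 3 or Wfs1KO replicate 1, 2 or 3 (adjusted p 0.0540 to 0.115). Txnip stood at -0.16 (adjusted p = 0.105), and passed with DESeq2 (0.0360). Of 19 glycolysis genes 4 fell, 1 rose and 14 did not pass, and adjusted over the list alone 4 fell and 4 rose (camera adjusted p = 0.669). Its median of 0.03 and its mean of 0.04 were above 0 while the test pointed down. Aldoc (-0.58), Pkm (-0.31), Pfkl (-0.22) and Eno2 (-0.21) fell, and Pgk1, named after its value was seen, rose (0.37). Pfkl lost its call without WT replicate 4 (adjusted p = 0.0553) and Eno2 without WT replicate 1, 2 or 3 or Wfs1KO replicate 1 (0.0559 to 0.0727). Pgk1 lost it without any 1 library other than WT replicate 2 (0.0588 to 0.105) and with the replicate block (0.0564). Of the markers of endothelial and of stellate cells, 11 of 14 and 3 of 14 rose in the same libraries (medians 0.49 and 0.57).

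Of 22 genes of the tricarboxylic acid cycle and pyruvate entry 5 fell, 2 rose and 15 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.377). The median was 0.0077 while the mean of -0.03 and the test pointed down. The pyruvate carboxylase gene Pcx (-0.54), Fh1 (-0.44) and Idh2 (-0.35) fell, as did Dlst (-0.16), while the aspartate aminotransferase gene Got1 (0.58) and Mdh1 (0.34) rose. Dlst and Mdh1 were named after their values were seen. Dlst lost its call without any 1 library other than WT replicate 1 or 2 (adjusted p 0.0584 to 0.146) and with the replicate block (0.0607). Of 73 genes of oxidative phosphorylation 5 rose, 0 fell and 68 did not pass, and 3 rose adjusted over the list alone (median 0.10, camera adjusted p = 0.0407, and adjusted p = 0.846 with an estimated correlation). The call was lost without WT replicate 1 (adjusted p = 0.0938), WT replicate 2 (0.117) or Wfs1KO replicate 2 (0.501, median 0.03), with the replicate block (0.0509), with DESeq2 (0.0592), with a filter of 1 CPM (0.0572) and with the acinar score as a covariate (0.109). The 5 were Uqcrq (0.48), Atp5g1 (0.45), Ndufa1 (0.38), Cox7b (0.27) and Atp5f1 (0.16), the last named after its value was seen. Cox7b lost its call without WT replicate 3 or 4 or Wfs1KO replicate 1 or 2 (0.0504 to 0.0683), and Atp5f1 without any 1 library other than WT replicate 4 (0.0598 to 0.138) and with the replicate block (0.0737). In the same comparison 11 of 14 members of the endothelial list (median 0.49) and 3 of 14 of the stellate list (median 0.57) rose.

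The list of cholesterol synthesis genes passed the preset test, pointing down. Of 21 members 6 fell, 0 rose and 15 did not pass, and 7 fell adjusted over the list alone (median -0.06, camera adjusted p = 0.0112, and adjusted p = 0.814 with an estimated correlation). Stard4, which encodes a sterol carrier, fell by 0.44 on the log2 scale (SE 0.08, adjusted p = 0.00251) and Srebf2, which encodes the pathway's transcription factor SREBP2, by 0.36. Without WT replicate 4 the median was -0.0061 and the list no longer passed (adjusted p = 0.0993), and without WT replicate 2 the median was -0.14. Of 14 genes of the hypoxia response 5 rose, 1 fell and 8 did not pass, and adjusted over the list alone 6 rose and 5 fell (median 0.21, camera adjusted p = 0.268), and the list passed with fry (0.00790). The adrenomedullin gene Adm (2.09), Egln3 (1.49), P4ha2 (0.46), P4ha1 (0.25) and Pdk1 (0.24) rose, and Vegfa fell (-0.22), the last 2 named after their values were seen. The largest 2 of these rises were of genes with few reads, Adm (0.362 ± 0.157 to 1.51 ± 0.573 CPM) and Egln3 (0.905 ± 0.193 to 2.57 ± 0.579 CPM). Pdk1 lost its call without Wfs1KO replicate 3 or 4 (adjusted p 0.0610 to 0.0627), and Vegfa without WT replicate 1, 2 or 3 or Wfs1KO replicate 1, 2 or 3 (0.0561 to 0.133). Across the same libraries endothelial markers had a median of 0.49 (11 of 14 rose) and stellate cell markers of 0.57 (3 of 14 rose).

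The list of secretory granule and exocytosis genes passed the preset test, pointing down. Of 26 members 7 fell, 1 rose and 18 did not pass, and adjusted over the list alone 8 fell and 2 rose (median -0.09, camera adjusted p = 0.0233, and adjusted p = 0.804 with an estimated correlation). The prohormone convertase gene Pcsk1 fell by 0.66 on the log2 scale (SE 0.06, adjusted p = 9.89e-06), and the syntaxin gene Stx1a by 0.52, while the synaptotagmin gene Syt4 rose by 0.37. The list did not pass without WT replicate 4 (median -0.04, adjusted p = 0.108) or Wfs1KO replicate 1 (0.0890), nor with the replicate block (0.0509). Of 27 genes of calcium handling 8 fell, 5 rose and 14 did not pass, and adjusted over the list alone 9 fell and 5 rose (median -0.08, camera adjusted p = 0.123), and the list passed with fry (0.0389). The inositol trisphosphate receptor gene Itpr3 (-0.52), the calcium channel genes Cacna1a (-0.48) and Cacna1c (-0.34) and the ER calcium pump gene Atp2a3 (-0.36) fell. Those that rose included, named after their values were seen, Itpr2 (0.78), Slc8a1 (0.21), Tmbim6 (0.21) and Calm2 (0.19). Slc8a1 lost its call without Wfs1KO replicate 4 (adjusted p = 0.0660), and Tmbim6 without WT replicate 1 or 2 or any 1 Wfs1KO library (0.0570 to 0.0932). Calm2 lost it without any 1 library other than WT replicate 4 (0.0543 to 0.120) and with the replicate block (0.0535). Cisd2, the gene mutated in another form of Wolfram syndrome, stood at -0.02 (SE 0.07, adjusted p = 0.860). Of 16 subunits of the vacuolar proton pump 2 fell, Atp6v0a1 (-0.29) and Atp6ap2 (-0.29), 0 rose and 14 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.669). The median was 0.02 while the mean of -0.02 and the test pointed down, and Atp6ap2 lost its call without WT replicate 3 or Wfs1KO replicate 1 (0.0511 to 0.0545). Of the other cell types, 11 of 14 endothelial markers (list median 0.49) and 3 of 14 stellate cell markers (list median 0.57) rose.

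Lists for oxidative stress, cell cycle, cell death, inflammation and early response genes did not pass the preset camera test. Of 20 NRF2 targets and antioxidant genes 4 rose, 0 fell and 16 did not pass, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.123), and the list passed with no filter (0.0278) and with fry (0.00847, but 0.0758 with the replicate block). The 4 were the haem oxygenase gene Hmox1 (1.01), Prdx1 (0.28), Sod1 (0.30) and Me1 (0.28). Sod1 lost its call without WT replicate 2 or 3 (adjusted p 0.0530 to 0.0549) and stood at 0.20 without Wfs1KO replicate 2, and Me1 without WT replicate 2, 3 or 4 or Wfs1KO replicate 2 or 4 (0.0854 to 0.138) and with the replicate block (0.0619). Of 30 cell cycle genes Ccnd2, the cyclin D2 gene, fell (-0.39), Rrm2 rose (0.61) and 28 did not pass, and adjusted over the list alone 1 fell and 0 rose (median -0.17, camera adjusted p = 0.488). Rrm2 lost its call without any 1 library other than WT replicate 2 or Wfs1KO replicate 4 (0.0530 to 0.0881). Of 19 targets of p53 and apoptosis genes 3 rose, 2 fell and 14 did not pass, and adjusted over the list alone 4 rose and 2 fell (median 0.14, camera adjusted p = 0.272), and the list passed with fry (0.0225, but 0.123 with the replicate block). Cdkn1a, the cell cycle inhibitor p21, rose by 1.12 (SE 0.11, adjusted p = 7.43e-05), Bcl2 by 0.47 and Fas, named after its value was seen, by 0.70, while Bcl2l11 (-0.48) and Sesn1 (-0.26) fell.

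Of 23 interferon response genes Oasl2 (-0.83), Ifit1 (-0.73) and Stat2 (-0.23) fell, 0 rose and 20 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.888). The median of 0.08 and the mean of 0.07 were above 0 while the test pointed down. Of 11 NF-kB targets and chemokines the adhesion molecule gene Icam1 rose (1.25), 0 fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.10, camera adjusted p = 0.669). Icam1 lost its call without WT replicate 1, 3 or 4 or Wfs1KO replicate 2 (adjusted p 0.0533 to 0.0658). Of 12 immediate early genes Jun (0.43), Ier2 (0.40) and Nr4a1 (0.92) rose, 0 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.36, camera adjusted p = 0.331). Nr4a1 lost its call without any 1 library other than WT replicate 2 or Wfs1KO replicate 4 (0.0699 to 0.0956).

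Endothelial cell markers, which label the islet's blood vessels, rose as a group. Of 14 members 11 rose, 0 fell and 3 did not pass, and 12 rose adjusted over the list alone (median 0.49, camera adjusted p = 2.44e-11, and adjusted p = 0.0636 with an estimated correlation). Pecam1 rose by 0.64 (SE 0.07, adjusted p = 3.14e-05), Eng by 0.67, Plvap by 0.62, Egfl7 by 0.54 and the VEGF receptor gene Kdr, the most abundant, by 0.40 (154 ± 12.4 to 204 ± 18.6 CPM). Of 14 markers of stellate cells, fibroblasts and pericytes the pericyte gene Rgs5 (0.70), Pdgfrb (0.54) and Acta2 (0.87) rose, 0 fell and 11 did not pass, and 4 rose adjusted over the list alone (median 0.57, camera adjusted p = 0.00378, and adjusted p = 0.634 with an estimated correlation). In replicates 3 and 4 alone the median of the stellate list was -0.09 (adjusted p = 0.479).

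Of 26 acinar cell markers Bhlha15, a transcription factor gene of secretory cells, rose (0.57), 0 fell and 25 did not pass, with the same counts adjusted over the list alone (median -0.38, camera adjusted p = 0.272). Without Wfs1KO replicate 4 the list passed the preset camera test, pointing down (median -0.99, adjusted p = 0.00147), and it passed with limma-voom (0.00165). With all libraries and an estimated correlation its camera adjusted p was 0.846. Its most abundant member Ctrb1 stood at -0.44 (SE 0.55, adjusted p = 0.667). Of 10 ductal cell markers 2 rose, the keratin gene Krt18 (0.46) and Spp1 (0.77), 1 fell and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.718). The median was -0.16 while the mean of 0.0033 and the test pointed up, and Krt7 stood at -0.14 (adjusted p = 0.200, and 0.0463 without Wfs1KO replicate 2). Spp1 lost its call without WT replicate 1 or Wfs1KO replicate 1 or 2 (adjusted p 0.0680 to 0.0771) and with the replicate block (0.0559). Of 16 macrophage and myeloid markers 0 rose and 0 fell, also adjusted over the list alone (median 0.41, camera adjusted p = 0.425, and 0.0259 with limma-voom), and Cd74 stood at 0.45 (adjusted p = 0.425). Of 10 lymphocyte markers 0 rose and 0 fell, also adjusted over the list alone (median 0.85, camera adjusted p = 0.562). The B cell gene Cd79a stood at -0.86 (adjusted p = 0.135), and passed without Wfs1KO replicate 4 (0.0423) and with the replicate block (0.0221). Of 8 Schwann cell and neuronal markers 1 rose, 0 fell and 7 did not pass, with the same counts adjusted over the list alone (median 0.25, camera adjusted p = 0.648). Of 5 red blood cell markers 0 rose and 0 fell, while 3 rose adjusted over the list alone (median 0.54, camera adjusted p = 0.331), and Hbb-bs stood at 0.43 (adjusted p = 0.0854, and 0.0438 without WT replicate 3).

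**Figure D3:**
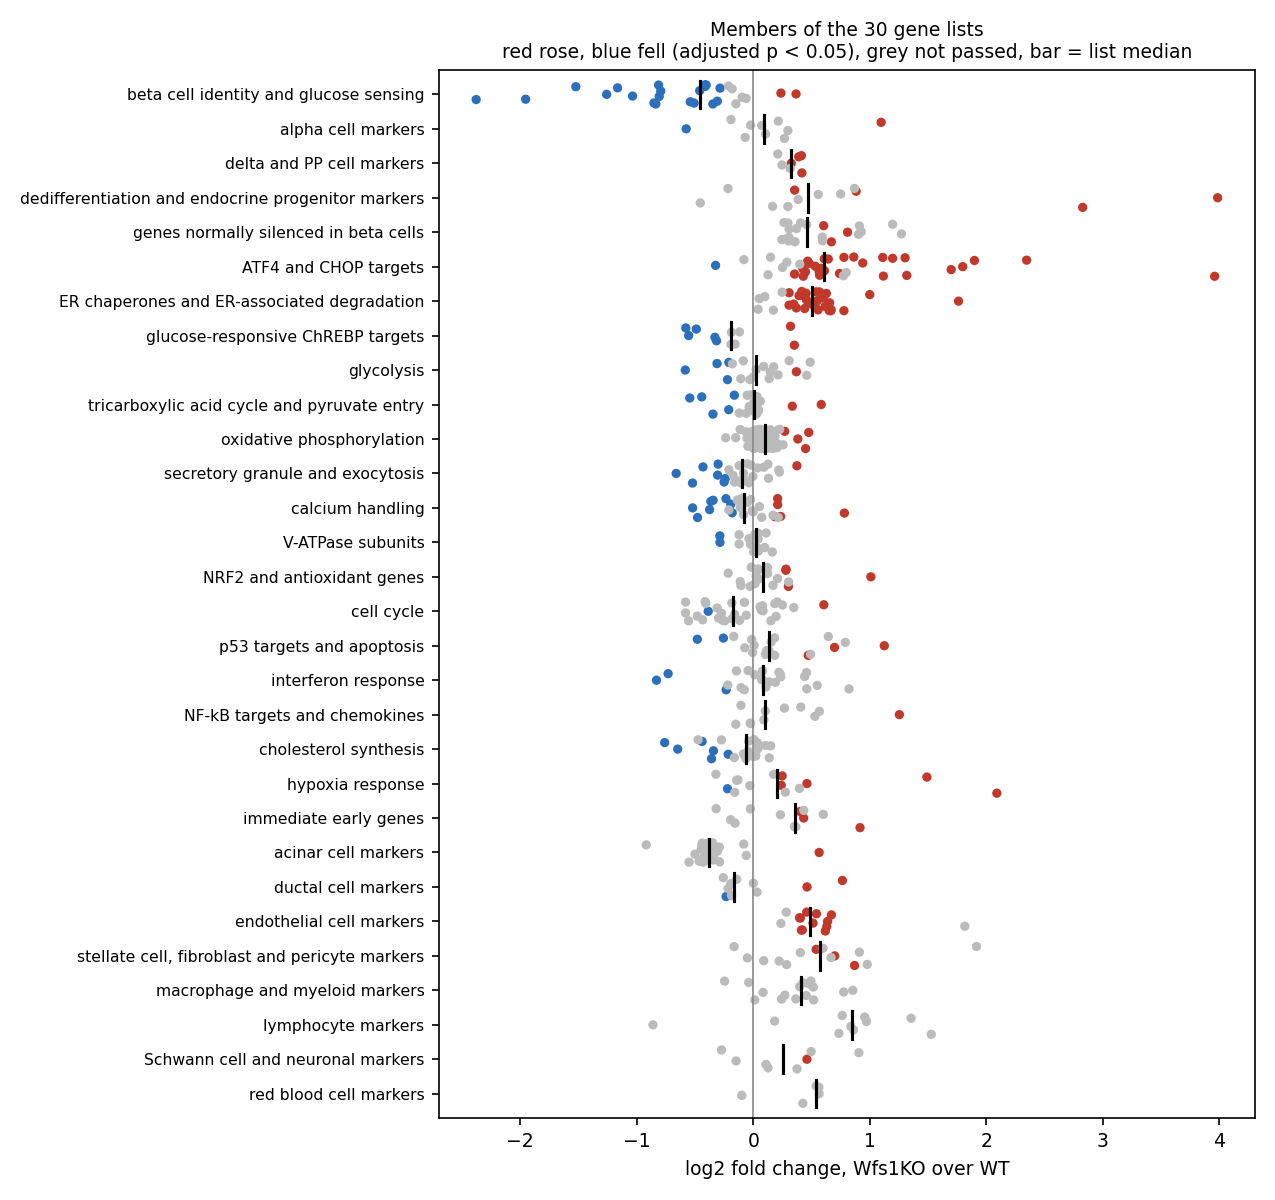
Log2 fold change (Wfs1KO over WT) of each tested member of the 30 gene lists, 1 point per gene, red where the gene rose, blue where it fell and grey where it did not pass, with a black bar at the list median. The beta cell list has its median at -0.46, the ER chaperones at 0.51 and the ATF4 and CHOP targets at 0.61.

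Called genes were not shown to be more frequent near Wfs1 than elsewhere. Within 20 Mb of Wfs1 on chromosome 5, 40 of 235 tested genes (17.0%) were called, against 2929 of 15497 (18.9%) in the rest of the genome (odds ratio 0.880, 95% interval 0.609 to 1.25, two-sided Fisher's exact test p = 0.502). In the deposited comparison 3043 genes had an adjusted p under 0.05, 1570 higher and 1473 lower in Wfs1KO. Of the 2970 genes called here 2797 (94.2%) were among them, all 2797 in the same direction. The authors' table gives log2 fold changes of -0.71 for Wfs1, -2.15 for Mafa, -0.77 for Ins2 and 3.46 for Aldh1a3. Some changes differed more in size, such as Areg (3.69 there, 5.04 here), Serpina7 (1.86 and 2.83) and Trib3 (0.83 and 1.70). Adm (0.87 there, 2.09 here), Ghsr and Me1 rose here but did not pass there, while Ddit3 and Txnip passed there but not here.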

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

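None of the tests in this part was chosen after its result was seen. Within each genotype, the highest and the lowest of the 4 libraries were compared with the rest for 7 measures of the libraries and for each named gene that is reported here, and a library was marked where its gap to the nearest other, over the group's whole range, was above Dixon's 95% critical value. Chance flags about 1 in 20 groups, and 14 of 254 groups were marked against 12.7 by chance, 6 in WT and 8 in Wfs1KO. No measure of the libraries (counts, exon share, acinar share or share of the most abundant genes) was marked. The rule looks for 1 library apart from the rest, so it cannot mark 4 libraries that divide in the middle. Exon share did so, at 60.0 to 66.9% in replicates 1 and 2 of both genotypes and 71.9 to 76.5% in replicates 3 and 4.

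In WT replicate 4, Slc7a11 stood at 0.638 CPM (1.85 to 2.05 in the others), Hmox1 at 4.17 CPM (6.75 to 7.22) and Ghsr at 3.88 CPM (5.40 to 5.62). In WT replicate 2, Selenos stood at 84.2 CPM (94.4 to 95.2 in the others) and Stat2 at 35.6 CPM (32.3 to 32.6). In WT replicate 3, Ier2 stood at 11.8 CPM (9.47 to 9.81 in the others).

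In Wfs1KO replicate 3, the glucagon gene Gcg stood at 24644 CPM (17412 to 18518 in the others) and Hmox1 at 10.2 CPM (13.2 to 13.5). In Wfs1KO replicate 1, Nkx6-1 stood at 232 CPM (266 to 273 in the others) and Stard4 at 33.0 CPM (31.2 to 31.2). In Wfs1KO replicate 2, Ndufa1 stood at 42.9 CPM (35.3 to 36.0 in the others), Cacna1c at 77.7 CPM (89.5 to 91.6) and Srebf2 at 135 CPM (149 to 152). In Wfs1KO replicate 4, Xbp1 stood at 358 CPM (323 to 327 in the others).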

How the results depend on the processing

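The settings using replicates 1 and 2 only, replicates 3 and 4 only, their contrast as a block, the exon share as a covariate, and Wfs1KO replicates 3 and 4 left out were chosen after the data were seen. The counts of genes higher and lower stayed within 1.5 times 1635 and 1335, and Wfs1 stayed lower and called, except under the settings named next. At an adjusted p under 0.01, 962 genes were higher and 782 lower and 7 lists passed. With a log2 fold change of at least 1, 131 genes were higher and 70 lower, and Wfs1 (-0.74) no longer passed, by construction. With an estimated correlation 3 lists passed in place of 12. In replicates 3 and 4 only, 964 genes were higher, 882 lower and 6 lists passed, against 1548, 1391 and 14 in replicates 1 and 2 only, with as many samples, and the cause was not tested. Leaving out each library in turn gave 1354 to 1460 genes higher, 1019 to 1299 lower, 10 to 13 lists and -0.83 to -0.71 for Wfs1. DESeq2 gave 1565 higher and 1465 lower and limma-voom 1781 and 1524.

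With the replicate block, 1603 genes were higher and 1329 lower, 10 lists passed, Wfs1 stood at -0.74 and the odds ratio of called genes within 20 Mb of Wfs1 at 0.950, and 2735 of the 2970 calls were shared. Among named genes and lists the block ended the calls of Trib3, Ghsr, Me1, Spp1, Iapp, Pgk1, Dlst, Atp5f1 and Calm2 and of oxidative phosphorylation and the secretory granule, gave calls to Ddit3 and Cd79a, and changed no other call of the preset camera test. Of the called genes named, the acinar score as a covariate ended 16 calls, no filter 11, DESeq2's size factors 6, the 20 most abundant genes left out 4, DESeq2 3 and limma-voom 1. Fry, which asks another question, gave calls to 4 lists, NRF2 (adjusted p = 0.00847), p53 (0.0225), hypoxia (0.00790) and calcium handling (0.0389), and ended those of 4, the silenced genes (0.0735), the secretory granule (0.0735), cholesterol synthesis (0.177) and oxidative phosphorylation (0.328). With the replicate block, fry no longer passed NRF2 (0.0758), p53 (0.123), delta and PP (0.0697) or stellate markers (0.184).

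The odds ratio near Wfs1, never past its threshold, crossed 1 with no filter (1.04), a log2 fold change of at least 1 (1.34), a window of 40 Mb (1.12) and in single left-out libraries (0.861 to 1.02). Other turns of direction concerned results that did not pass, except oxidative phosphorylation and the median of the stellate list (-0.09 in replicates 3 and 4 only), and their cause was not tested. Cisd2 turned to 0.0080 in replicates 3 and 4 only and ran from -0.067 to 0.029 over left-out libraries. In replicates 3 and 4 only, Ppy stood at -0.13, oxidative phosphorylation at a median of -0.051, NF-kB targets at -0.090 and macrophage markers at 0.019. The test's direction turned for interferon genes with no filter (median 0.096), limma-voom (0.161), fry (0.080), the exon share (0.152), replicates 1 and 2 only (0.138) and Wfs1KO replicates 3 and 4 left out (0.200), for glycolysis in the last 2 settings (0.085 and 0.103), and for alpha cell markers with the acinar score as a covariate (0.0073) and in the last setting (-0.031). Over left-out libraries medians ran from -0.020 to 0.185 for alpha cells, -0.187 to 0.031 for ductal cells, 0.035 to 0.192 for interferon genes, 0.113 to 0.572 for macrophages and 0.013 to 0.281 for NF-kB targets. With 4 libraries per genotype and simulated 1.5-fold changes found in 63.9% of cases, smaller changes may go uncalled.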

Other observations

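The tests on remaining Wfs1 reads, on beta cell number, on acinar RNA and on abundant genes, and the lists and genes of the next 2 paragraphs, were chosen after the results were seen, and the count of splits with an estimated correlation was added after the count with the preset correlation was seen.

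Of 34 genes of coat proteins and cargo receptors of transport between ER and Golgi, a list chosen because its members were seen to rise, 26 rose and 0 fell (median log2 fold change 0.32). The ER retention receptor gene Kdelr3 rose from 9.18 to 25.1 CPM (log2 fold change 1.45, adjusted p = 5.36e-07), and the cargo receptor gene Tmed3 (0.79) and the COPI gene Copb2 (0.28) rose as well. Of 79 tested genes of cytosolic ribosomal proteins, chosen in the same way, 38 rose and 0 fell (median 0.27), among them Rps28 (0.44). No test of these lists is given, since it would run on the values that picked them.

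Further genes, chosen after their values were seen, were lower in all 4 Wfs1KO libraries. The neuronatin gene Nnat fell by 1.66 on the log2 scale, the transcription factor gene Sox4 by 1.54, Gad1, which encodes the enzyme that makes GABA, by 1.30, and the monoamine oxidase gene Maob by 1.28. The growth factor gene Egf rose (0.88, adjusted p = 5.40e-05) beside Areg, and the receptor gene Egfr fell by 0.57. Nnt, a mitochondrial transhydrogenase gene, stood at 37.7, 34.9, 60.2 and 97.0 CPM in WT replicates 1 to 4 and at 116, 107, 97.7 and 80.2 CPM in Wfs1KO replicates 1 to 4 (log2 fold change 0.80, adjusted p = 0.188, and 0.0180 without WT replicate 4).

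The genotype split was compared with the other splits of the 8 libraries into 4 and 4, 35 in all. Over all 35, chance can be excluded for the number of called genes, since only the genotype split (1 of 35) gave 2970 and the highest other gave 107, and likewise for the 1635 higher and the 1335 lower genes (highest other 107 in 1 direction). The split with 107 (WT replicates 1, 3 and 4 with Wfs1KO replicate 4) parts 2 of the 4 pairs of replicate numbers, and the other splits that part all 4 pairs, as the genotype split does, called fewer genes than it. For the number of lists called by camera with the preset correlation chance cannot be excluded, since 12 of 35 splits gave 12 or more lists. The highest other gave 18 while parting all 4 pairs. It grouped WT replicates 1, 2 and 3 with Wfs1KO replicate 4, so part of the genotype contrast remained in it. The cause of its count was not tested. With an estimated correlation only the genotype split of the 35 gave 3 lists (1 of 35, highest other 1), which excludes chance over all splits without regard to pairs. Only 8 splits part all 4 pairs, too few for a share under 0.05, and with the replicate block and an estimated correlation no list passed (lowest adjusted p = 0.172). Taken list by list, only the genotype split gave a p as small for beta cell identity, dedifferentiation, ATF4 and CHOP targets, ER chaperones and endothelial markers, while 5 to 25 of 35 splits did so for the other 7 lists that passed. For endothelial markers the margin was small, with a camera p of 3.26e-12 against 5.86e-12 in the nearest other split. The smallest camera p of other splits was 9.15e-12 for beta cell identity and 6.28e-05 for dedifferentiation. It was 9.66e-19 for ATF4 and CHOP targets and 2.82e-18 for ER chaperones.

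Beta cell genes were lower in Wfs1KO islets (median -0.46), and fewer beta cells, acinar RNA or the share of abundant genes could account for that. With the acinar score as a covariate the median was -0.48 and with the 20 most abundant genes left out -0.49, and the list passed camera both times, which argues against acinar RNA and the share of abundant genes. Ins1, Ins2 and Iapp are among those 20, so the second median is of the list without them. Fewer beta cells would lower no gene further than the insulin genes, yet 5 of 27 members (Mafa, Slc2a2, Trpm5, Sytl4 and Ffar1) had 95% intervals below that of Ins2, which argues against cell number as the whole cause for those 5. The interval of Ins1 was -0.60 to -0.22. Those of Pdx1 (-0.94 to -0.74), Slc30a8 (-1.17 to -0.90), Gipr (-1.02 to -0.68) and Ero1lb (-0.95 to -0.67) lay below it. Measured against Ins1, this argues against cell number as the whole cause for these members too. How reads shared by Ins1 and Ins2 were counted is not stated. Neither fewer beta cells nor lower expression describes Iapp and Tmem27, which rose, but for the other members that fell fewer beta cells cannot be told apart from lower expression per cell, since the rise of endothelial over alpha cell markers that would speak against it was 0.80, 0.16, -0.0061 and 0.57 in mean log2 CPM in replicates 1 to 4 (mean 0.379, two-sided exact permutation p = 0.250 over the 16 reassignments within pairs, too few for a p under 0.05, and 0.0857 without regard to pairs, where 0.0286 is the smallest possible). A response of beta cells to loss of Wfs1 stays a hypothesis, untested here.

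Reads of Wfs1 remained in Wfs1KO islets at 0.599 of the WT level. WT RNA mixed into the Wfs1KO libraries would set a floor under every gene, yet 18 genes of at least 5 CPM in WT were lower by more than the lower 95% bound of Wfs1 (edgeR glmTreat), with Mafa at a ratio of 0.194 and Slc2a2 at 0.348. That argues against mixing as the whole source of the Wfs1 reads. A smaller share of WT RNA, up to the lowest of these ratios (0.110, Caps2), is not excluded by this test. This test replaced a looser one whose value, once seen, lay close to its own bound. A transcript still made from the targeted allele may be the source, but with a ratio of 0.599 over all exons and counts per exon not analysed here it cannot be told apart from other sources. Flanking DNA of another mouse strain around the targeted gene would put more called genes near Wfs1. The odds ratio within 20 Mb of 0.880 (95% interval 0.609 to 1.25) argues against a large excess there. With 235 tested genes in the window, the test cannot show whether a few of the calls came from flanking DNA. Strain differences elsewhere in the genome were not tested.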
